A study of Homo sapiens with 6 samples.

How the data were processed

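The series holds 6 Affymetrix arrays of RNA from Hs578T breast cancer cells with inducible HOXA5, taken at 0 h, 6 h and 9 h in each of 2 experiments. Per the labels the cells were seeded 24 h before induction on a 10 cm dish. The values deposited by the authors are 1 intensity per probe set and array, linear and positive, with no scaling between arrays: the highest and the lowest 2% trimmed mean of the 6 arrays differed 5.49-fold. The software that made these intensities is not given in the sources used here. The inducing agent and its dose are not given there either. Probe sets were named from the platform's probe table, which lists 20114 of them, 19071 with 1 symbol and 1043 with several; 2169 probe sets had no symbol. Symbols were read through Entrez gene numbers for 19059. HOXA5 is named by 0 probe sets of that table, so its level was not analysed here. No genome was used, so no coordinates are given.

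The groups were 0 h, 6 h and 9 h with 2 arrays each, and the comparisons were 6 h with 0 h, 9 h with 0 h, 9 h with 6 h, and both induced times with 0 h. Because the trimmed means did not lie within 5% of each other, the values were quantile normalised, floored at the 25th percentile of the positive values (12.7 intensity units, 3.67 on the log2 scale) and log2 transformed. Of the probe sets, 68 Affymetrix controls were left out of the tests, and 18360 with at least 2 of the 6 arrays above the floor were tested, of which 15976 carried 1 symbol, for 10444 genes. A total of 3535 of these genes had several probe sets, and the one with the highest mean over all arrays stood for the gene. Changes were fitted with lmFit, contrasts and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, with 3 residual degrees of freedom, and adjusted by Benjamini-Hochberg over the probe sets of each comparison, at a threshold of 0.05. All p-values are two-sided. The ± values are standard errors of that fit. A change to or from a group with both arrays at the floor is given as a lower bound against the floor where both arrays of the other group lie above it.

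The experiment number marks a shared batch of RNA per the labels, so it pairs the arrays across times. Deviations from the group means correlated between arrays of the same experiment at 0.247 (0 h and 6 h), 0.336 (0 h and 9 h) and 0.391 (6 h and 9 h). The fit without the experiment was set as the main design and the paired fit (replicate block, 2 residual degrees of freedom) as the alternative, and its values stand beside a result where it changed a call or a count. The 6 h array of experiment 2 carries a lot line of experiment 1 in its label while its title and description name experiment 2; the title was followed, and the lot line was run as another block.

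Gene lists numbered 27, with 813 different genes in all: immediate-early, NF-kB and cytokines, endoplasmic reticulum and integrated stress response, oxidative phosphorylation, sterol synthesis, interferon, mesenchymal and matrix, cytoskeleton and adhesion, genes linked to HOXA5, HOX genes, proliferation, p53 targets, apoptosis, heat shock, hypoxia and glycolysis, TGF-beta and YAP targets, growth factors, LXR, RXR and PPAR genes, proteasome, splicing factors, cytosolic ribosome, housekeeping, and markers of luminal epithelial, endothelial, leukocyte, nerve and muscle, and erythroid and hepatic cells. Lists with at least 5 tested genes were tested with camera in limma with a preset correlation between genes of 0.01 and again with an estimated one, adjusted over the lists. With the estimated correlation camera also uses the few residual degrees of freedom of the fit, in place of those from the many genes. Members were also adjusted over the list alone. The lists, the comparisons, the tests and the first set of alternatives were chosen before the data were examined.

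Genes were named by a rule. For 6 h and 9 h against 0 h it takes the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold and of the same direction in both experiments, filled to 10 by the smaller of the changes within the experiments where fewer passed, and 5 and 5 for the other comparisons. It also takes every tested gene linked to HOXA5, and up to 4 members per list with the largest change together with members past the threshold. Members of the lists named because they passed with the experiment as a term, and the genes said to be so, were chosen after their values were seen.

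The number of arrays, 2 per group, limits the precision of each value. On simulated data (20 runs of 18360 probe sets, 200 of them changed) the fit without the experiment recovered 0% of log2 changes of 1 and 3.45% of changes of 2 at 9 h, and the paired fit 20.4% and 81.6%, with 8.55 false calls on average. These data were drawn from the paired model, with its experiment effect, its spread and independent noise, so they favour the paired fit. The list test recovered a list shifted by 0.5 in 20 of 20 runs, with the experiment as a block. Genes were drawn independently there and without an experiment effect, so this recovery need not hold for correlated genes or smaller shifts. The correlation of the changes at 6 h and 9 h was set against 100 draws of unchanged groups with shared 0 h arrays, and list medians against 10000 random lists of the same size matched on mean intensity.

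Alternatives were the replicate block, the lot line as a block, unscaled values, arrays centred on the median, floors at the 10th and 40th percentile, a pseudocount in place of the floor, no filter on dim probe sets, only probe sets above the median, no intensity trend, only the compared arrays, the mean of a gene's probe sets, the estimated correlation, and leaving out each array in turn. Combinations of the replicate block with these, and gene families taken by symbol, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Splits of the arrays into other groups were not counted, since each group holds 2 arrays.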

Results

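Gene expression was measured in Hs578T cells, an established human breast cancer line, that carried an inducible HOXA5 gene. HOXA5 is a homeobox transcription factor, and the title of the series puts its target genes as the question. RNA was taken before induction (0 h) and 6 h and 9 h after it, in each of 2 experiments, so that each of the 3 groups held 2 arrays. The arrays were Affymetrix chips, read as 1 intensity per probe set. The labels describe the experiments as 2 batches of RNA and state no further replication. The limma p-values below measure the spread between these 6 arrays, moderated toward that of probe sets of like intensity. Those of camera with the preset correlation set the genes of a list against the other genes. They measure spread across genes and not replication of the experiments. The level of HOXA5 itself was not analysed here, because the probe table used here names no probe set for it. With 0 uninduced arrays at 6 h or 9 h among the samples used here, time in culture and the inducing agent go with the groups.

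The arrays differed in brightness. The median deposited intensity was 95.8 and 49.1 in the 0 h arrays of experiments 1 and 2, 18.7 and 39.1 at 6 h, and 48.7 and 42.4 at 9 h. In unscaled values the median log2 change of all tested genes was -1.36 at 6 h and -0.57 at 9 h, so the changes below are relative to the whole array. Ribosomal RNA probe sets read 1.12, 1.90 and 4.34 times the array median at 0, 6 and 9 h in experiment 1, and 0.176, 0.170 and 0.328 times in experiment 2. The cre control probe sets read 65.2, 207 and 179 times the array median in experiment 1, and 47.4, 37.1 and 48.9 times in experiment 2. The ratio of 3' to 5' signal of GAPDH, a sign of RNA quality, was 0.863 and 0.975 at 0 h, 0.910 and 1.09 at 6 h, and 1.31 and 1.12 at 9 h. That of ACTB was 1.09 and 1.04, 1.03 and 0.918, and 1.82 and 1.06. The number of arrays limits the precision of every value.

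Relative to the whole array, induction for 6 h came with higher levels of genes that cells switch on soon after a stimulus and of genes of the NF-kB pathway, and with lower levels of genes of the respiratory chain and of sterol and fatty acid synthesis. As groups, the first 2 had an adjusted p = 0.423 with an estimated correlation and the others an adjusted p = 0.755 with an estimated correlation. EGR1, an early growth response transcription factor, was 5.38-fold higher at 6 h than at 0 h, a log2 change of 2.43 ± 0.52 (standard error, n = 2 arrays per group). IER2, another immediate-early gene, was 2.70-fold higher (log2 change 1.43 ± 0.32). The cytokine LIF had a log2 change of 2.51 ± 0.58, and NFKBIA, the inhibitor that NF-kB itself switches on, 2.60 ± 0.66 (1.54 without the 0 h array of experiment 1). NDUFA1, a subunit of respiratory complex I, had a log2 change of -1.58 ± 0.72 (-0.64 without the 6 h array of experiment 2), and SCD, a fatty acid desaturase, -1.20 ± 0.66 (-0.39 without the 0 h array of experiment 1).

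The 27 tested genes of the immediate-early list rose as a group at 6 h (camera adjusted p = 2.2e-10), with a median log2 change of 0.74 that was -0.60 in unscaled values, where all genes shifted by -1.36. The call was lost with an adjusted p = 0.423 with an estimated correlation. The median was 0.83 in experiment 1 and 0.79 in experiment 2, and 21 members were higher and 1 lower in both experiments. EGR1 and IER2 passed when adjusted over the list alone (limma adjusted p = 0.0330 each), the 2 members that did so, and 0 passed over all probe sets; with the experiment as a term 12 and 0 did. MAFF, a small MAF transcription factor, and the stress factor ATF3 had log2 changes of 1.84 and 1.42 and did not pass. They had 0.61 and 0.55 without the 0 h array of experiment 1, and 3.04 and 2.26 without that of experiment 2. Without the 6 h array of experiment 2 they had 1.11 and 0.61, and ATF3 had 2.25 without that of experiment 1. IER2 and ATF3 lay at -0.032 and -0.20 in unscaled values.

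The 29 tested genes of the NF-kB and cytokine list rose as a group (camera adjusted p = 1.4e-06), with a median of 0.94 that was -0.32 in unscaled values. It did not hold with an adjusted p = 0.423 with an estimated correlation. The experiments gave medians of 0.62 and 0.97, and 19 members were higher and 3 lower in both. LIF and TNFAIP6, a hyaluronan-binding protein induced by TNF, each had an adjusted p = 0.0448 and NFKBIA 0.0495 when adjusted over the list alone, 3 members in all against 0 over all probe sets, and 10 against 0 with the experiment as a term. Only 1 of the 2 TNFAIP6 probe sets had that sign, with 1 of its 0 h arrays at the floor. CXCL8, the neutrophil chemokine interleukin-8, had a log2 change of 2.75 ± 1.27 (1.23 without the 6 h array of experiment 1, 4.32 without that of experiment 2) and did not pass.

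The 41 tested oxidative phosphorylation genes fell as a group at 6 h (camera adjusted p = 3.2e-06), with a median log2 change of -0.30. The group did not pass with an adjusted p = 0.755 with an estimated correlation. The medians were -0.16 and -0.52 in experiments 1 and 2, and 29 members were lower and 1 higher in both. No member passed by limma when adjusted over the list alone or over all probe sets, where 875 of the tested probe sets had an unadjusted p under 0.05. In the fit with the experiment as a term 3 members fell when adjusted over the list alone and 0 over all. COX7C, a cytochrome oxidase subunit, had a log2 change of -0.91, NDUFC1, of complex I, -0.79, and ATP5PO, of ATP synthase, -0.89, with 1 of the 2 ATP5PO probe sets of that sign. COX7C and NDUFC1 were -0.37 and -0.27 without the 6 h array of experiment 2, and -1.44 and -1.31 without that of experiment 1. The 18 sterol synthesis genes fell as a group (median -0.35, -0.69 and -0.15 by experiment, 10 lower and 2 higher in both, camera adjusted p = 0.00983). That call was lost with an adjusted p = 0.755 with an estimated correlation. MSMO1, a sterol demethylating enzyme, had a log2 change of -1.33, INSIG1, which holds back sterol synthesis, -1.01, and the fatty acid synthase FASN -0.88. Without the 0 h array of experiment 1 these were -0.61, -0.50 and -0.51, and MSMO1 was -2.03 without that of experiment 2. Adjusted over the list alone 0 sterol genes passed, and 2 fell with the experiment as a term. Without the 6 h array of experiment 2 neither call held (adjusted p = 0.307 and 0.424), and without the 0 h array of experiment 1 that of the sterol list did not (0.600, median -0.041). The respiratory median was -0.59 without the 6 h array of experiment 1 and -0.14 without that of experiment 2, and the sterol median -0.57 without the 0 h array of experiment 2.

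The 31 interferon response genes had a median log2 change of -0.46 at 6 h (-0.44 and -0.06 by experiment), 15 being lower and 6 higher in both (camera adjusted p = 0.0476). This did not hold with an adjusted p = 0.755 with an estimated correlation. Members moved both ways: the immunoproteasome subunit PSMB8 and the antiviral TRIM22 had log2 changes of -1.08 and -1.04, while IRF7, a transcription factor of the interferon response, and the antiviral MX1 had 1.46 and 1.25. TRIM22 was -0.50 without the 0 h array of experiment 1 and -1.57 without that of experiment 2, and MX1 0.72 without the latter; each had 1 array at the floor, at 6 h and at 0 h. None of the list passed by limma adjusted over the list alone, and 1 member rose and 3 fell so with the experiment as a term. The call ended without the 6 h array of experiment 1 (adjusted p = 0.128, median -0.24) or 2 (0.307, median -0.22), the 0 h array of experiment 1 (0.600, median -0.15) or the 9 h array of experiment 2 (0.0508), and in unscaled values (0.0791).

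No probe set passed for 6 h against 0 h by limma, among 18360 tested, with 875 at an unadjusted p under 0.05 where chance gives 918. With the experiment as a term in the fit the counts were again 0 (lowest adjusted p = 0.0653) and 1781. Some probe sets passed with that term when any 1 of the 6 arrays was left out, but such fits hold a group of 1 array and give no support. In both experiments 227 probe sets were at least 2-fold higher and 230 at least 2-fold lower, beside 218 that moved 2-fold in opposite directions. The genes with the largest changes shared by both experiments did not pass either. GADD45B, a stress response gene, had a log2 change of 2.48 ± 0.39 and the same sign in all 4 of its probe sets. PCDH12, a protocadherin, was at the floor in both 0 h arrays and at least 5.83-fold higher at 6 h. Among the others on the higher side were CYP11B2, the aldosterone synthase (2.41), AADAC, an arylacetamide deacetylase (2.25), GMEB1 (2.23), the microtubule-associated protein MAPT (2.04, with 2 of its 4 probe sets of that sign) and HHLA1 (1.82). On the lower side were the protocadherin PCDHB3 (-2.95), the phosphatase subunit PPP4C (-2.79), the sorting nexin SNX17 (-2.31), the deubiquitinase MINDY1 (-2.07), C11orf71 (-2.04), the actin regulator WASL (-2.03 on the brighter of 2 probe sets, the other of opposite sign), GDPD5 (-2.00) and KPTN (-1.76). Of their 2 arrays per group, CYP11B2 and AADAC had 1 at the floor at 0 h, and PCDHB3 and KPTN 1 at 6 h, so these changes depend on the floor. NME3, a nucleoside diphosphate kinase, and the growth factor GDF3 were at the floor in both 6 h arrays, at least 4.31-fold and 3.55-fold lower than at 0 h.

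**Figure D1:**
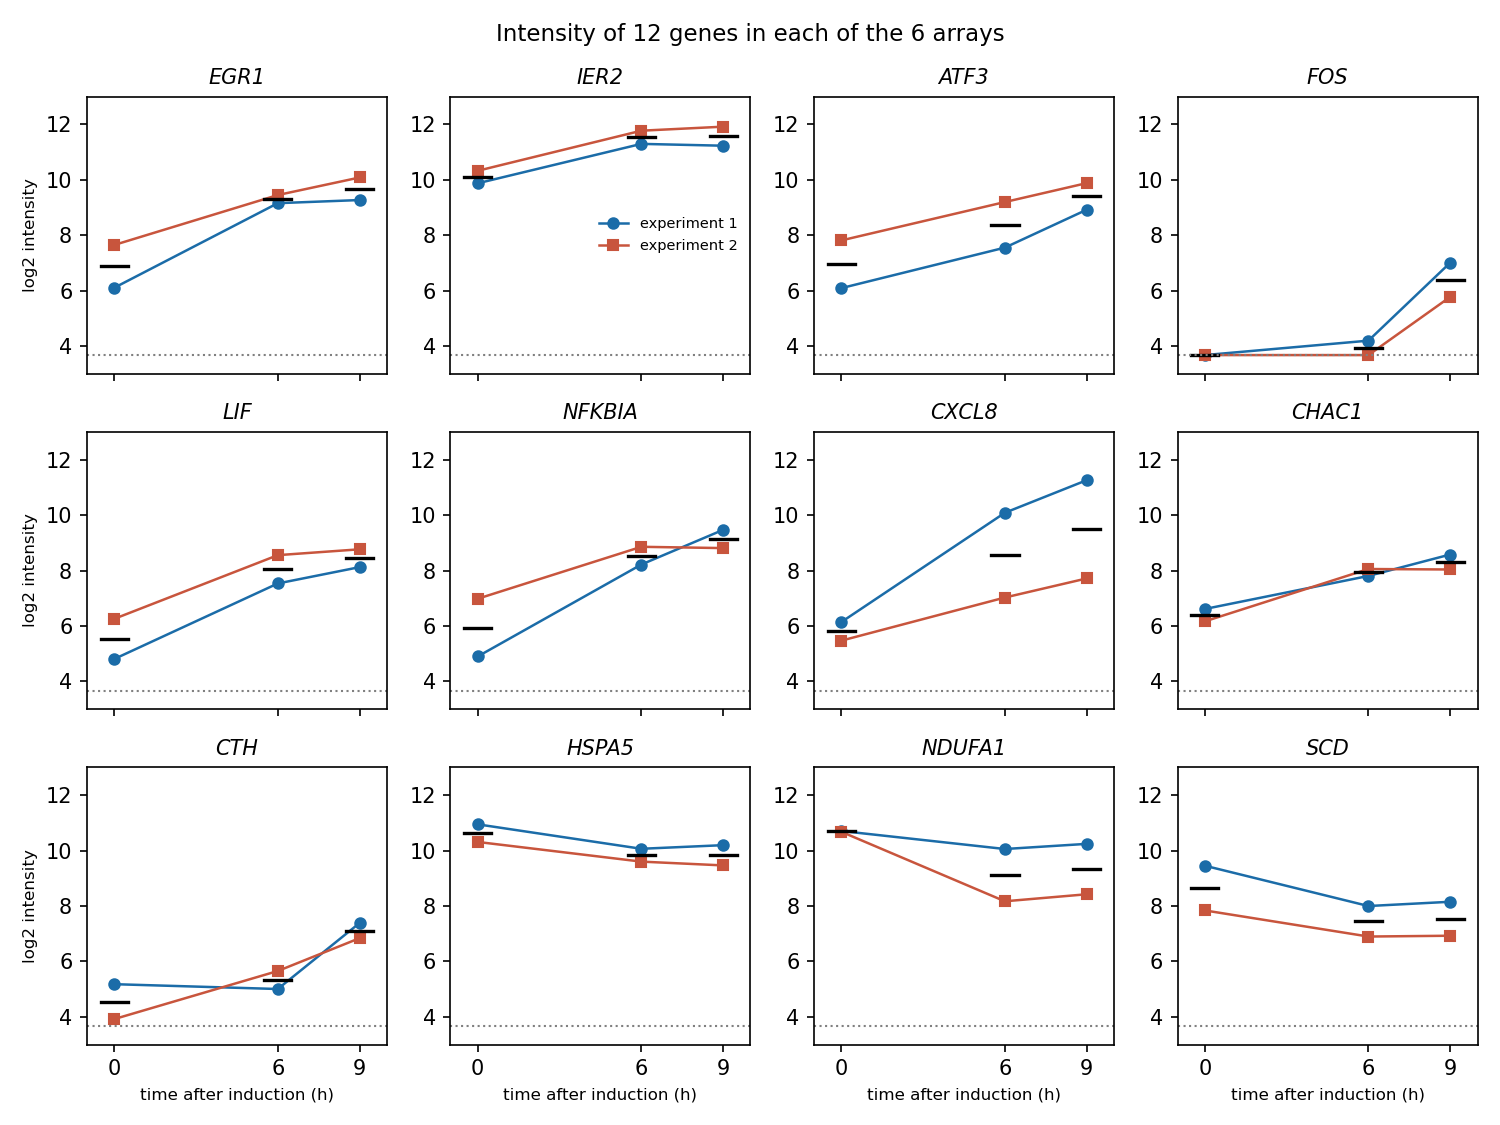
Log2 intensity (quantile normalised) of 12 genes in each of the 6 arrays against hours of induction, with experiment 1 in blue circles, experiment 2 in red squares, the mean of the 2 arrays of a group as a black bar and the floor of 3.67 as a dotted line. EGR1, LIF and NFKBIA lie higher at 6 h and 9 h than at 0 h in both experiments, with log2 changes at 9 h of 2.80, 2.91 and 3.20.

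At 9 h the immediate-early and NF-kB genes were again above their 0 h level, relative to the whole array, and the endoplasmic reticulum and integrated stress response list rose with members that moved both ways. As groups, the first 2 had an adjusted p = 0.356 with an estimated correlation and the last an adjusted p = 0.508 with an estimated correlation. EGR1 was 6.97-fold higher than at 0 h (log2 change 2.80 ± 0.52), and MAFF 7.48-fold (2.90 ± 0.79), by 4.01 in experiment 1 and 1.80 in experiment 2. FOS, a subunit of the AP-1 transcription factor, was at the floor in both 0 h arrays and at least 6.58-fold higher at 9 h. CXCL8 was 12.8-fold higher (log2 change 3.68 ± 1.27), by 5.12 in experiment 1 and 2.25 in experiment 2 (1.87 without the 9 h array of experiment 1). CHAC1, which degrades glutathione and is a target of the stress factor ATF4, was 3.78-fold higher (1.92 ± 0.34), while the endoplasmic reticulum chaperone HSPA5 had a log2 change of -0.80 ± 0.35 (-0.49 without the 0 h array of experiment 1 and -0.43 without the 9 h array of experiment 2).

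The immediate-early list rose as a group at 9 h (camera adjusted p = 5.4e-16), with a median log2 change of 1.18 (0.60 unscaled), 1.44 and 1.00 in the experiments, and 23 of 27 members higher and 0 lower in both. The call was lost with an adjusted p = 0.356 with an estimated correlation. By limma 13 members passed when adjusted over the list alone and 0 over all probe sets, and with the experiment as a term 21 and 6 did. Those 6 were EGR1 and ATF3 (adjusted p = 0.00890 each), IER2 (0.0144), and MAFF, KLF10 and JUN (0.0298 each), with log2 changes of 2.80, 2.45, 1.47, 2.90, 1.97 and 1.58. Without the 0 h array of experiment 1 ATF3 had 1.57 and MAFF 1.67. KLF10 is a TGF-beta inducible zinc finger factor and JUN the partner of FOS in AP-1. All 4 JUN probe sets were higher.

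The NF-kB and cytokine list rose as a group (median 1.02, 0.88 and 0.44 by experiment, 17 higher and 3 lower in both, camera adjusted p = 2.0e-05). It was lost with an adjusted p = 0.356 with an estimated correlation. The median was 0.38 in unscaled values, 0.39 without the 9 h array of experiment 1, 0.57 without that of experiment 2 and 0.66 without the 0 h array of experiment 1. Its limma counts were 4 when adjusted over the list alone and 0 over all probe sets, and 14 and 4 with the experiment as a term. The last 4 were LIF (adjusted p = 0.00890, log2 change 2.91), CXCL8 (0.0355), NFKBIA (0.0409, log2 change 3.20, by 4.57 and 1.83 in the experiments) and TNFAIP3, a ubiquitin-editing brake on NF-kB (0.0452, log2 change 2.38, by 3.33 and 1.42).

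The 29 genes of the endoplasmic reticulum and integrated stress response list rose as a group (camera adjusted p = 8.1e-04), with a median of 0.23 (0.25 and 0.38 by experiment) that was -0.34 in unscaled values, where all genes shifted by -0.57, and 15 members higher and 4 lower in both. The call was lost with an adjusted p = 0.508 with an estimated correlation, and with 0.0655 when the 0 h array of experiment 2 was left out (median 0.050). The median was 0.51 without the 0 h array of experiment 1 and 0.48 without the 9 h array of experiment 2. When adjusted over the list alone 4 members passed by limma: CTH, an enzyme of cysteine synthesis (log2 change 2.56 ± 0.57, adjusted p = 0.0187), CHAC1 (0.0169), the transcription factor CEBPG (1.53 ± 0.30, 0.0169) and asparagine synthetase ASNS (1.53 ± 0.32, 0.0187). Over all probe sets 0 passed, and 3 did with the experiment as a term. Adjusted over the list alone with that term, 12 members rose and 2 fell, the latter being the chaperones HSPA5 (adjusted p = 0.00542) and PDIA4 (0.0213, log2 change -1.25 on the brighter of 2 probe sets, the other of opposite sign, -2.21 without the 9 h array of experiment 1 and -0.25 without that of experiment 2).

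The oxidative phosphorylation list fell as a group at 9 h (median -0.32, -0.20 and -0.42 by experiment, 25 lower and 1 higher in both, camera adjusted p = 2.8e-05). That was lost with an adjusted p = 0.530 with an estimated correlation, and with 0.0921 when the 9 h array of experiment 2 was left out (median -0.13, or -0.49 without that of experiment 1). No member passed by limma, in the list alone or over all probe sets, where 1360 had an unadjusted p under 0.05. With the experiment as a term 6 members fell when adjusted over the list alone, among them CYC1, cytochrome c1 (log2 change -0.96), and the cytochrome oxidase subunits COX7B (-0.92) and COX7A2 (-0.88), which were -0.47 and -0.39 without the 9 h array of experiment 2. The sterol synthesis list fell as a group as well (median -0.43, -0.54 and -0.32 by experiment, 10 lower and 3 higher in both, camera adjusted p = 0.00895). This call was lost with an adjusted p = 0.630 with an estimated correlation, with 0.174 when the 9 h array of experiment 2 was left out, and with 0.513 when the 0 h array of experiment 1 was (median -0.18, or -0.88 without that of experiment 2). By limma 0 of its members passed in the list alone and, with the experiment as a term, 5 fell, among them DHCR7, the last enzyme of cholesterol synthesis (-1.49, from -2.25 to -0.72 with 1 of the 0 h arrays left out). FASN, SCD and INSIG1 had log2 changes of -1.20, -1.11 and -1.10; SCD and INSIG1 had -0.30 and -0.59 without the 0 h array of experiment 1, SCD -1.90 without that of experiment 2, and FASN -0.73 without the 9 h array of experiment 1. MVD, of the mevalonate pathway, was at the floor in both 9 h arrays, at least 2.35-fold lower (log2 change -1.23, and -0.70 without the 0 h array of experiment 1).

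Genes of the mesenchymal and matrix list, 40 tested, had a median log2 change of -0.39 at 9 h (-0.35 and -0.27 by experiment), with 27 lower and 7 higher in both. The camera adjusted p was 0.0657, and 0.00325 with the experiment as a term, which became an adjusted p = 0.766 with an estimated correlation. COL5A1, a collagen chain, had a log2 change of -1.01, and SNAI1, a repressor of E-cadherin, was at the floor in both 9 h arrays, at least 3.10-fold lower. Its relative SNAI2 went the other way, with a log2 change of 1.35 ± 0.27. Adjusted over the list alone with the experiment as a term, 5 members fell and 1 rose, these 3 genes among them. The 30 cytoskeleton and adhesion genes had a median of -0.38 (-0.36 and -0.02 by experiment, 16 lower and 5 higher in both), with an adjusted p = 0.0711, or 0.0412 with the experiment as a term and then 0.683 with an estimated correlation. Its 3 members that fell with that term, in the list alone, were the myosin light chain MYL9 (-1.23), the calponin CNN2 (-0.94) and the actinin ACTN4 (-0.78).

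Of the 8 genes linked to HOXA5 in earlier work, 5 could be tested, and none passed at either time in the fit without the experiment. PTN, the growth factor pleiotrophin, had log2 changes of 1.95 ± 0.90 at 6 h and 1.40 ± 0.90 at 9 h on its brightest probe set, the only 1 of its 4 with that sign. At 9 h it was 0.037 without the array of experiment 2 and 2.74 without that of experiment 1, and at 6 h 1.11 without the array of experiment 2. That probe set passed when adjusted over the list alone with the experiment as a term (limma adjusted p = 0.00254 and 0.0221, and 0.00267 for both times pooled), and not over all probe sets (0.293 and 0.161). TWIST1, a mesenchymal transcription factor, had -0.88 and -1.02, with 1 of its 9 h arrays at the floor. Without the array of experiment 2 at that time these were -0.26 at 6 h and 0.0038 at 9 h, and without that of experiment 1 -1.52 and -2.03. The apoptotic proteases CASP8 and CASP2 had -0.13 and 0.40, and 0.10 and 0.06. CASP8 at 9 h was 0.22 without the 9 h array of experiment 2. The list's camera adjusted p was 0.812 at 6 h and 0.587 at 9 h. The endothelial receptor KDR was at the floor in both 0 h arrays and in 1 array of each later time, so no fold is given.

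By limma 0 of the 18360 probe sets passed at 9 h, with 1360 at an unadjusted p under 0.05 (918 by chance) and a lowest adjusted p of 0.543. With the experiment as a term 66 passed (60 higher, 6 lower, in 54 genes), with 2545 at an unadjusted p under 0.05, and all 66 had the same direction in both experiments. The count of 66 fell to 0 with that term in unscaled values, without the filter on dim probe sets or without the intensity trend. It rose when any 1 of the 6 arrays was left out, but such fits hold a group of 1 array, so the rise is no support for the calls. With the lot line of the labels as the block in place of the experiment, 0 probe sets passed. The fits without and with the experiment leave few degrees of freedom, 3 and 2, and moderate each spread toward that of probe sets of like intensity. With the experiment as a term, CXCL8 (5.12 and 2.25 by experiment) had a standard error of 0.55, and AADAC (2.68 and 2.67) one of 0.45. A pass with that term is therefore no measure of close agreement between the 2 experiments. In both experiments 393 probe sets were at least 2-fold higher, 226 at least 2-fold lower and 131 opposite. Of the genes with the largest changes shared by both experiments, GADD45B (2.68 ± 0.39, adjusted p = 0.00890), AADAC (2.68 ± 0.62, 0.0497) and LOXL1, a lysyl oxidase of elastic fibres (-1.72 ± 0.31, 0.0427), passed with the experiment as a term, as did LIF, EGR1 and CXCL8. The ± values are from the fit without the experiment, and with it as a term they were 0.26, 0.45 and 0.28. Genes of this kind that did not pass with the term were ZNF23 (2.78), GMEB1 (2.40), the bradykinin receptor BDKRB1 (2.29), SLC29A3, a nucleoside transporter (-2.12), MINDY1 (-1.98), VSIG4 (-1.89) and the melanocortin receptor MC2R (-1.82). AADAC and ZNF23 had 1 array at the floor at 0 h, and SLC29A3 and VSIG4 1 at 9 h. GMEB1 at 0 h and MC2R at 9 h lay near the floor of 3.67 (means 4.02 and 3.78), and the change of MC2R was as small as -0.65 over the alternatives. The xylosyltransferase XYLT2, YWHAH-AS1, NME3, PRPH2 and the cytokine IL19 were at the floor in both 9 h arrays, at least 4.77-, 4.76-, 4.31-, 4.16- and 4.09-fold lower. Chosen after their values were seen, further genes past the threshold with that term were CCNL1, a cyclin of the splicing machinery (2.10), SAT1, a polyamine acetyltransferase (2.08), GEM, a small GTPase (2.18, or 1.16 without the 0 h array of experiment 1 and 1.39 without the 9 h array of experiment 2), TIPARP (1.79), PMAIP1, the pro-apoptotic NOXA (2.01, with 0.0315 when adjusted over the apoptosis list alone without the term), and UQCR10, of respiratory complex III (-1.34).

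**Figure D2:**
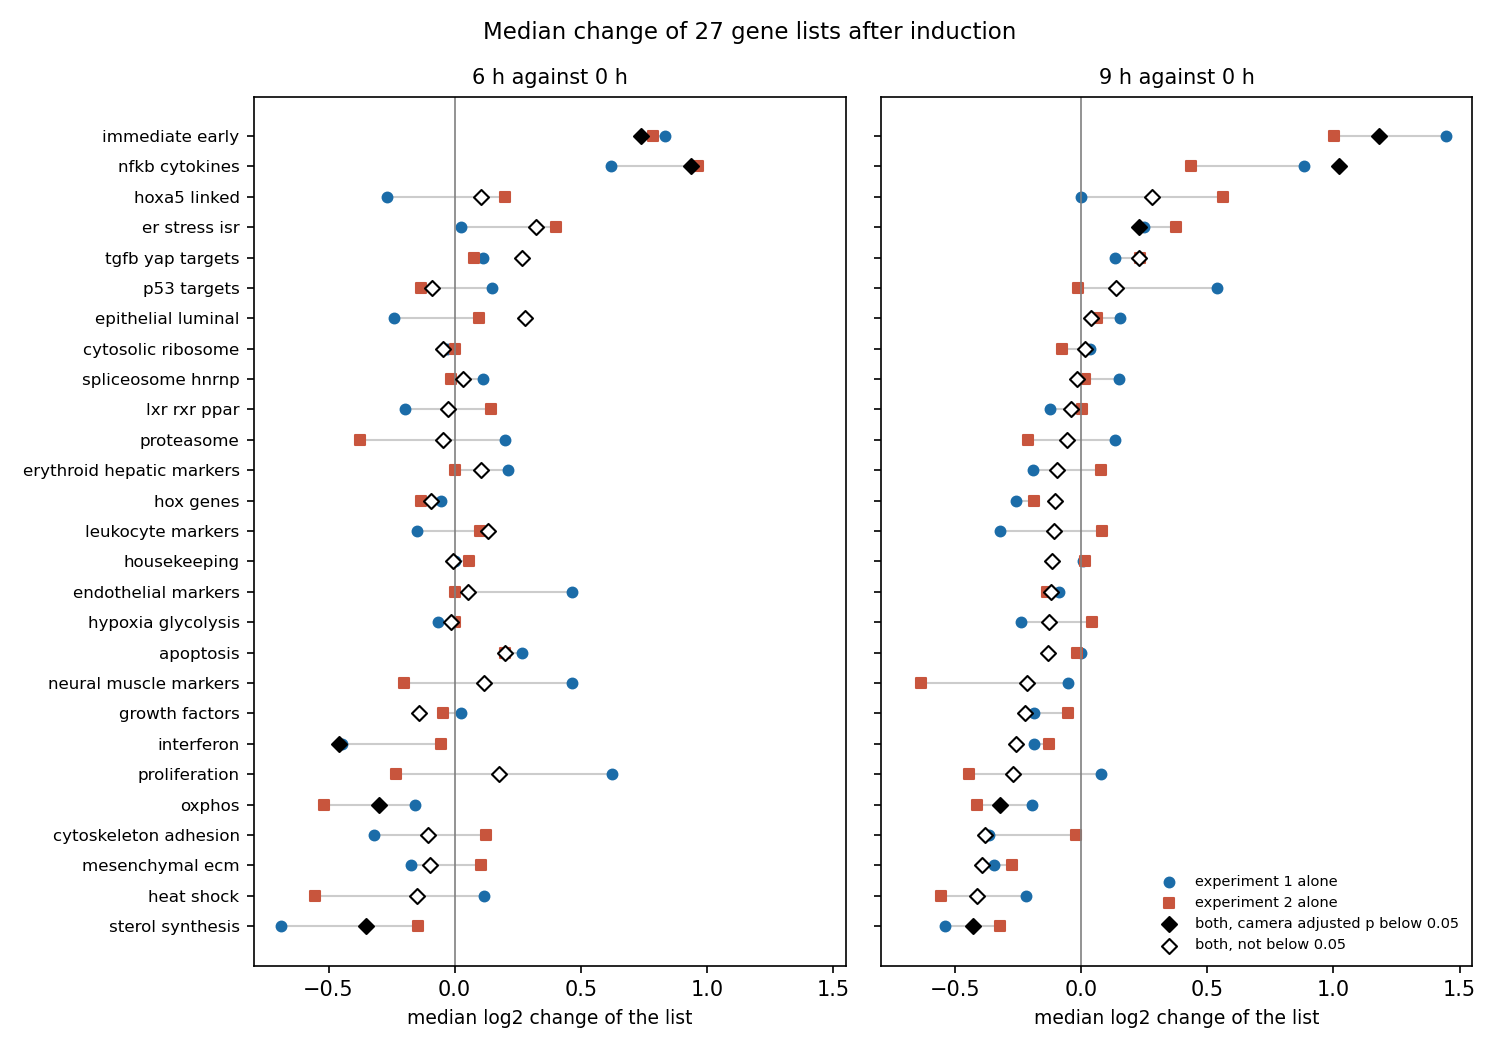
Median log2 change against 0 h of the tested genes of each of the 27 gene lists at 6 h and at 9 h, in experiment 1 alone (blue circles), experiment 2 alone (red squares) and both (diamonds, filled where the camera adjusted p with the preset correlation is below 0.05). The immediate-early list lies highest at 9 h, at 1.18, and the oxidative phosphorylation list lies below 0 in both experiments at both times; unscaled, the immediate-early median was -0.60 at 6 h and 0.60 at 9 h.

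Between 6 h and 9 h the immediate-early and stress response lists had medians above 0 and the proliferation list had one below it, in calls that rest on the dim 6 h array of experiment 1 and were lost with an adjusted p = 0.785 with an estimated correlation. FOS was 5.49-fold higher at 9 h than at 6 h (log2 change 2.46 ± 0.51), and passed by limma when adjusted over the list alone (adjusted p = 0.0476), with 1 of the 2 arrays at 6 h at the floor, so that the fold depends on the floor. CTH had a log2 change of 1.78 and ASNS 1.15, while the mitotic kinases PLK1 and AURKB had -1.06 and -1.02 (-0.60 and -0.54 without the 9 h array of experiment 1). None of these 4 passed.

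The immediate-early list had a median of 0.37 between 6 h and 9 h (camera adjusted p = 0.00214), and the stress response list 0.23 (0.0206). Both were lost with an adjusted p = 0.785 with an estimated correlation. The NF-kB list did not pass (median 0.18, adjusted p = 0.784, 6 higher and 6 lower in both experiments). The 40 proliferation genes had a median of -0.30 that was 0.67 in unscaled values, where all genes shifted by 0.78 (camera adjusted p = 9.9e-04, lost unscaled at 0.494), by -0.48 and -0.14 in the experiments, with 22 lower and 3 higher in both. This too was lost with an adjusted p = 0.785 with an estimated correlation. Without the 6 h array of experiment 1 the adjusted p was 0.366 for immediate-early (median 0.22), 0.123 for stress response and 0.758 for proliferation genes (median -0.082). Without the 6 h array of experiment 2 the immediate-early and proliferation medians were 0.74 and -0.63. The stress response call also ended without the 6 h array of experiment 2 (0.160, median 0.35) or the 9 h array of experiment 1 (0.175, median 0.11), and its median was 0.50 without the 9 h array of experiment 2. Adjusted over the list alone 1 immediate-early and 0 stress response members passed by limma, and 3 and 3 with the experiment as a term. NR4A1, a nuclear receptor of the immediate-early list, MAFF and ATF3 had log2 changes of 1.29, 1.06 and 1.02, and 0.63, 0.32 and 0.20 without the 6 h array of experiment 1; NR4A1 had 1 array at the floor at 6 h. Lists past the threshold numbered 5 with the experiment as a term: p53 targets (median 0.32, adjusted p from 0.0505 to 0.00662) and mesenchymal genes (median -0.28 that was 0.69 in unscaled values, from 0.0965 to 0.00802) were the additions. With that term the 5 had an adjusted p = 0.808 with an estimated correlation.

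Probe sets past the threshold between 6 h and 9 h numbered 0 by limma, with 968 at an unadjusted p under 0.05, and 0 and 1696 with the experiment as a term (lowest adjusted p = 0.473). Fits with that term and 1 of the 6 arrays left out hold a group of 1 array, so passes there give no support. Of the largest changes shared by both experiments, GOLPH3L had a log2 change of 2.47, WDR13 2.08, the tight junction protein CLDN15 1.93, ATXN8OS -2.05, NIPAL2 -1.87 and MAPT -1.84 (2 of its 4 probe sets with that sign). Of their 2 arrays per group, GOLPH3L, WDR13 and CLDN15 had 1 at the floor at 6 h and ATXN8OS 1 at 9 h, so these changes depend on the floor. TRAPPC12, of a vesicle tethering complex, was at the floor in both 6 h arrays and at least 6.57-fold higher at 9 h. The immunoglobulin heavy chain IGHM and TESPA1 were at the floor in both 9 h arrays, at least 5.50-fold and 4.17-fold lower, with 2 of the 3 IGHM probe sets of that sign.

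With both times pooled as induced, LIF was 6.56-fold higher (log2 change 2.71 ± 0.50, 2 arrays against 4), EGR1 6.12-fold (2.61 ± 0.45) and GADD45B 5.99-fold (2.58 ± 0.34). NFKBIA had a log2 change of 2.90 (1.84 without the 0 h array of experiment 1) and IER2 of 1.45. PCDHB3, with 1 array at the floor at 6 h, had a log2 change of -2.33, WNT5B, a secreted WNT ligand, -2.08, MINDY1 -2.02 and PPP4C -1.96, and NME3 was at the floor in all induced arrays, at least 4.31-fold lower.

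The immediate-early list rose as a group (median 0.94, -0.028 unscaled, camera adjusted p = 3.3e-16, 23 higher and 0 lower in both experiments), as did the NF-kB list (median 1.07, 0.11 unscaled, adjusted p = 2.9e-07). The NF-kB median was 0.51 without the 9 h array of experiment 1 and 0.69 without the 0 h array of experiment 1. Both calls were lost with an adjusted p = 0.238 with an estimated correlation. The stress response list rose (median 0.26, -0.82 unscaled, adjusted p = 0.00495) and the oxidative phosphorylation list fell (median -0.28, adjusted p = 4.0e-07), and both were lost with an adjusted p = 0.529 with an estimated correlation. The sterol list fell (median -0.37, adjusted p = 0.00259), lost with an adjusted p = 0.652 with an estimated correlation. Adjusted over the list alone 13 immediate-early, 3 NF-kB, 2 stress response, 0 respiratory and 0 sterol genes passed by limma. In the paired fit 19, 14 and 10 rose, and 3 stress response, 8 respiratory and 4 sterol genes fell. The stress response call ended without the 0 h array of experiment 2 (0.321, median 0.15), without the 6 h array of experiment 1 (0.0533) and unscaled (0.320), the sterol call without the 0 h array of experiment 1 (0.470, median -0.16) or the 6 h array of experiment 2 (0.0512), and the sterol median was -0.67 without the 0 h array of experiment 2. With the experiment as a term the interferon list (adjusted p from 0.119 to 0.0472) and the mesenchymal list (from 0.219 to 0.0404) were added, and no list passed with an estimated correlation (lowest adjusted p = 0.595). By limma 0 probe sets passed, with 1136 at an unadjusted p under 0.05. In the fit with the experiment as a term 30 did, 27 higher and 3 lower, and 27 of the 30 were also among the 66 at 9 h. Leaving out any 1 of the 6 arrays raised that count, but such fits hold a group of 1 array, so the rise is no support for the calls. The 30 included LIF, GADD45B and EGR1 (adjusted p = 0.00847 each), IER2 (0.00971) and NFKBIA (0.0496), but not AADAC (log2 change 2.46, 0.0525) or GMEB1 (2.31, 0.0631).

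The changes at 6 h and at 9 h were correlated across the 18360 probe sets (Pearson r = 0.558), and 68.5% of probe sets had the same sign. Both comparisons share the 0 h arrays, which alone gave simulated unchanged groups an r of 0.499 on average (0.485 to 0.518 over 100 draws) and 66.7% of the same sign. The covariance was 0.175 against 0.116 simulated. The draws took the spread of the fit without the experiment and held no experiment effect, so they leave out the pairing of the arrays. The gap to the simulated values is therefore no measure of a shared change. Between 6 h of one experiment and 9 h of the other, which share no array, r was 0.177 and 0.138. The same change in the 2 experiments correlated at 0.143 at 6 h and 0.306 at 9 h. These values are across genes, which are not independent replicates.

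The remaining lists did not pass at 9 h. Closest were heat shock genes (median -0.41, adjusted p = 0.122), proliferation (-0.27, 0.122), p53 targets (0.14, 0.137) and markers of nerve and muscle (-0.21, 0.137). In experiments 1 and 2 the proliferation medians were 0.08 and -0.44 and those of p53 targets 0.54 and -0.01, so the experiments differed in sign. HOX genes had a median of -0.10 (0.268), endothelial markers -0.12 (0.376), growth factors -0.22 (0.424), interferon genes -0.26 (0.424), targets of TGF-beta and YAP 0.23 (0.546), hypoxia and glycolysis genes -0.13 (0.552), proteasome genes -0.06 (0.664), luminal epithelial markers 0.04 (0.664, and a median of -0.05 with arrays centred on their median), LXR, RXR and PPAR genes -0.04 (0.731) and housekeeping genes -0.12 (0.731, and 0.06 with arrays so centred). In 5 lists the median and the direction tested by camera differed in sign: splicing factors (-0.02, 0.424), cytosolic ribosome (0.01, 0.560), apoptosis (-0.13, 0.731), erythroid and hepatic markers (-0.10, 0.762) and leukocyte markers (-0.11, 0.995). Adjusted over the list alone by limma, 2 apoptosis genes, 1 p53 target and 1 marker of nerve and muscle passed. In the paired fit 4 apoptosis genes and 4 p53 targets rose, 3 hypoxia genes rose and 2 fell, 3 growth factors rose and 1 fell, 1 interferon gene rose and 2 fell, and 2 markers of nerve and muscle and 1 heat shock, 1 housekeeping and 1 proteasome gene fell. At 6 h the stress response list did not pass (median 0.32, adjusted p = 0.151), though 6 of its members rose and 1 fell in the list alone in the paired fit. In unscaled values the 9 h median of every list in this paragraph was below 0. Markers of other cell types gave 5 lists with medians between -0.21 and 0.04 at 9 h.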

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

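The test of the oxidative phosphorylation list against the cytosolic ribosome list was chosen after the result was seen, and the other tests of this part before.

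Immediate-early genes were higher after induction, by a median log2 of 0.74 at 6 h and 1.18 at 9 h relative to the array (-0.60 and 0.60 in unscaled values). As a group they did not pass with an estimated correlation (camera adjusted p = 0.423 at 6 h and 0.356 at 9 h). The uneven quality of the experiment 1 arrays is argued against as the whole cause, since in experiment 2 alone the median lay at percentile 100 of 10000 matched random lists at 6 h and at percentile 100 at 9 h. Such ranks draw genes within 1 pair of arrays and do not measure replication. The proliferation list at 6 h lay at percentile 100 in experiment 1 and 0.35 in experiment 2. A response to time in culture, to handling or to the inducing agent cannot be told apart from a response to HOXA5, because 0 uninduced arrays at 6 h or 9 h were among the samples used here. The rise may therefore belong to HOXA5, to the inducing agent, to time in culture or to handling, and the level of HOXA5 was not analysed here. In experiment 2 the GAPDH ratio of 3' to 5' signal was 0.975, 1.09 and 1.12 at 0, 6 and 9 h, and that of ACTB 1.04, 0.918 and 1.06. A part of RNA quality within experiment 2 was not tested.

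Oxidative phosphorylation genes were lower, by a median log2 of -0.30 at 6 h and -0.32 at 9 h, relative to the array (-1.85 and -0.95 unscaled, where all genes shifted by -1.36 and -0.57). In experiment 2 alone the median lay at percentile 0 of matched random lists at 6 h and 0.02 at 9 h. This argues against the quality of the experiment 1 arrays as the whole cause, but such ranks draw genes within 1 pair of arrays and do not measure replication. The fall was larger in experiment 2 (medians -0.52 at 6 h and -0.42 at 9 h) than in experiment 1 (-0.16 and -0.20). A part of the quality of the experiment 2 arrays was not tested. The median lay at percentiles of at most 0.04 at 9 h over 3 scalings, but a factor per array moves all genes alike and leaves such a rank nearly fixed, so an effect of scaling cannot be told apart by it. If a lower yield of short, abundant transcripts acted on both lists alike, it would lower the cytosolic ribosome list as far. The oxidative phosphorylation median lay below the ribosome median by -0.33, with a 95% bootstrap interval from -0.46 to -0.16. That interval draws genes and not arrays, and the equal fall was assumed, so a lower yield stays open. An effect of HOXA5, of time or of the inducing agent stays open as untested, and the calls were lost without the 6 h and the 9 h array of experiment 2 (adjusted p = 0.307 and 0.0921) and at 6 h with an adjusted p = 0.755 with an estimated correlation and at 9 h with an adjusted p = 0.530 with an estimated correlation.

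The GAPDH ratio of 3' to 5' signal, from control probe sets outside the comparisons, was 1.12 in the lower of the 9 h arrays, above both 0 h arrays (0.863 and 0.975). The ACTB ratio was 1.82 and 1.06 at 9 h against 1.09 and 1.04 at 0 h, so its lower 9 h array lay within the 0 h range. Among the genes named in the text, those that moved in opposite directions at 6 h and at 9 h in both experiments were singled out. They had been named for a large change from 6 h to 9 h, so such movement follows in part from that choice. From 6 h to 9 h AURKB had a log2 change of -1.02, GOLPH3L 2.47, ATXN8OS -2.05 and NIPAL2 -1.87, and IGHM, at the floor in both 9 h arrays, -2.46 or lower on 1 of its 3 probe sets, with 2 of the 3 of that sign. GOLPH3L had 1 of its 2 arrays at the floor at 6 h and ATXN8OS at 9 h. The test of these differences, the limma comparison of 9 h with 6 h, gave each an adjusted p of 0.932, and 0.473 with the experiment as a term.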

How the results depend on the processing

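The combinations with the replicate block were chosen after seeing the data, the other alternatives before. With the processing otherwise as reported, the fit without the block called 0 probe sets, and the replicate block gave 66 at 9 h, 30 for induced against 0 h, and 5 lists for 9 h against 6 h where 3 passed without it. It also moved the counts adjusted over the list alone. With the lot line as the block 0 probe sets passed at 9 h, 5 lists passed for 9 h against 6 h, and CASP2 at 6 h reversed to -0.053. The cause was not tested for any of the changes in this part. With the estimated correlation 0 lists passed in each comparison (0 at 6 h, 0 at 9 h, 0 for 9 h against 6 h, 0 for induced), with the block or without it. That setting also rests on the few residual degrees of freedom of the fit, so a lost call need not stem from correlation within a list. The apoptosis list at 6 h went from a camera adjusted p of 0.160 to 0.755, with an estimated correlation of -0.0062.

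Without scaling the lists past the threshold were 9 at 6 h, 8 for 9 h against 6 h and 8 for induced, and 9 probe sets passed for induced. Together with the block the lists were 10, 8 at 9 h, 8 and 9. Unscaled values, with or without the block, reversed the medians of the immediate-early list at 6 h (-0.60) and for induced (-0.028), of the NF-kB list at 6 h (-0.32), of the stress response list at 9 h (-0.34) and for induced (-0.82), and of proliferation for 9 h against 6 h (0.67). They reversed IER2 (-0.032), ATF3 (-0.20) and CASP2 (-1.24) at 6 h, and CASP8 (-0.13) and CASP2 (-0.50) at 9 h. Centring on the median gave 6 lists for 9 h against 6 h, and with the block 5, with 78 probe sets at 9 h and 25 for induced. Without the filter on dim probe sets 24, 12, 18 and 17 passed at 6 h, 9 h, 9 h against 6 h and induced, and 0 at 9 h once the block was added, where 5 lists passed for 9 h against 6 h.

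With the block, the floor at the 10th percentile gave 44 probe sets at 9 h, 18 for induced and 5 lists for 9 h against 6 h. The floor at the 40th percentile gave 7 at 6 h, 128 at 9 h and 79 for induced. The pseudocount gave 17, 243 and 129, with 5 lists for 9 h against 6 h and 8 for induced, and the brighter probe sets alone gave 20, 296 and 199, with 6 lists for 9 h against 6 h. With the block, unscaled values and no intensity trend each gave 0 at 9 h. The 66 were shared in full with the pseudocount, 64 with the floor at the 40th percentile and 48 with median centring.

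Leaving out each array in turn gave 4 to 7 lists at 6 h, 3 to 7 at 9 h, 0 to 5 for 9 h against 6 h and 4 to 8 for induced, and 0 probe sets without the block. With the block the lists were 4 to 8, 6 to 9, 3 to 5 and 5 to 10. The probe sets called with the block, from 1 residual degree of freedom, are given in the order of the arrays left out, 0 h, 6 h and 9 h, experiment 1 before experiment 2. They were 151, 54, 7, 4, 212 and 178 at 6 h, 460, 252, 328, 341, 260 and 373 at 9 h, 5, 46, 0, 0, 3 and 73 for 9 h against 6 h, and 334, 134, 157, 81, 493 and 349 for induced. The 66 at 9 h were nearly all among them. Larger sets drawn from 5 of the same 6 arrays make such overlap likely, so it is no test of the 66. A lone array was assumed to vary like the other groups. Changes of these genes reversed when an array was left out: CASP2 ranged from -0.11 to 0.33 at 6 h and from -0.15 to 0.29 at 9 h, CASP8 from -0.35 to 0.089 at 6 h, and TWIST1 from -2.03 to 0.0038 at 9 h. With the block CASP2 reversed to -0.14 without the 0 h array and -0.21 without the 6 h array of experiment 2 at 6 h, and at 9 h to -0.18 without the 0 h array of experiment 2 and -0.0043 without the 9 h array of experiment 1. CASP8 at 6 h reversed to 0.18 without the 0 h array and 0.055 without the 6 h array of experiment 1. The correlation of 0.558 between 6 h and 9 h moved to 0.177 and 0.138 between different experiments, which share no 0 h array. Of all comparisons of single genes under the alternatives, 2201 without the block and 1426 with it kept direction and side of the threshold, 1 and 635 came to pass it and 12 and 11 reversed. Of list medians 269 and 253 kept both, 49 and 29 no longer passed and 6 and 6 reversed. The planned level of HOXA5 gave no value. Depth on these arrays is signal over background: the deposited median intensity ran from 18.7 in the 6 h array to 95.8 in the 0 h array of experiment 1.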

Other observations

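The gene families taken by symbol and their tests, the RBM test included, were chosen after the calls were seen, and the lists of splicing, hypoxia, apoptosis and heat shock genes before.

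Genes that regulate splicing differed among themselves at 9 h. CLK1, a kinase of splicing factors, had a log2 change of 1.82 ± 0.56, the splicing factors SRSF6 1.05 ± 0.40, TRA2B 0.93 ± 0.25 and SRSF11 1.28 ± 0.31 (1 of its 3 probe sets with that sign), while the core spliceosome proteins SNRPD3 and SNRPF had -1.22 ± 0.43 (-0.80 without the 9 h array of experiment 2) and -1.07 ± 0.29. With the experiment as a term and adjusted over the list alone 9 of the 43 splicing genes rose and 2 fell, and the list's median was -0.02. In the family of SR proteins with CLK and cyclin L genes the median of 15 genes was 0.74 (0.092 in unscaled values, where all genes shifted by -0.57), with 11 higher and 2 lower in both experiments (camera adjusted p = 1.6e-06, adjusted p = 0.0887 with an estimated correlation). That family holds 2 genes past the threshold with the experiment as a term; without them the median was 0.58 (camera adjusted p = 4.2e-04, adjusted p = 0.141 with an estimated correlation). Zinc finger genes with ZNF symbols, 205 tested, had a median of 0.43 that was -0.12 unscaled, with 117 higher and 18 lower in both (camera adjusted p = 2.7e-11, adjusted p = 0.0372 with an estimated correlation, or 0.0740 with the experiment as a term). The tRNA synthetases had a median of 0.56 over 15 genes that was -0.028 unscaled (1.9e-04, adjusted p = 0.134 with an estimated correlation, and 0.00163 without 1 gene past the threshold in the paired fit, with 0.141 once the correlation was estimated), and mitochondrial ribosome genes -0.15 over 50 (0.00727, adjusted p = 0.269 with an estimated correlation). The mitochondrial ribosome median lay at percentile 6.7 of random lists matched on mean intensity, within their middle 95%. Those of the SR, ZNF and tRNA synthetase families lay at percentile 100, but these families were chosen after the calls were seen.

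Single members of lists that did not pass as groups also stood out at 9 h. VEGFA, an angiogenic growth factor, had a log2 change of 1.37 ± 0.38 with all 4 probe sets of that sign, and DDIT4, an inhibitor of mTOR signalling, 1.83 ± 0.64. Without the 0 h array of experiment 2 these were 0.87 and 0.86, and DDIT4 was 2.81 without that of experiment 1. MCL1, a survival protein, had 1.36 ± 0.31 in 5 of 5 probe sets of that sign (limma adjusted p = 0.0465 when adjusted over the list alone), BIRC2, an inhibitor of apoptosis, 1.22 ± 0.38, and the death receptor TNFRSF10B 1.01 ± 0.26. The small heat shock protein HSPB1 had -1.08 ± 0.30 (-0.69 without the 9 h array of experiment 1) and the tubulin TUBB -0.83 ± 0.24. Over all probe sets 0 of these passed by limma, among 1360 with an unadjusted p under 0.05. With the experiment as a term 2 other probe sets of MCL1 did (log2 changes 1.85 and 1.62, adjusted p = 0.0409 and 0.0304).

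The RBM family of RNA-binding proteins passed at 9 h with the preset correlation (26 genes, median 0.035 and -0.51 unscaled, camera adjusted p = 0.0299), and not with the estimated one (adjusted p = 0.231). Without the 2 members past the threshold in the paired fit it did not pass (median -0.011, camera adjusted p = 0.146). A candidate explanation is the brightness of its probe sets: its median, close to 0, lay at percentile 67.81 of random lists matched on mean intensity, which decides nothing about it. The mean moderated t, a measure added after the median was seen, lay at percentile 99.33, but the family was taken after the calls were seen and holds 2 of the called genes, so this excludes nothing and brightness stays open.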
